A study of Homo sapiens with 32 samples.

How the data were processed

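The series profiled Caco-2, an established human colon carcinoma line whose cells take on features of absorptive enterocytes after they reach confluence, on a 2-colour spotted array of transporter and ion channel genes. There were 32 arrays. Cells grown in flasks gave 12 arrays, cells grown on what the labels call filters A gave 12, and cells grown on filters B gave 8. Each format was sampled at 5 days and at 1, 2 and 3 weeks, with 3 arrays per time in flasks and in filters A and 2 in filters B. What sets filters A apart from filters B is not given in the sources used here. On every array channel 1 held 5-day RNA of the same format and channel 2 held RNA of the time point, so the 5-day arrays compare 5-day RNA with itself and served as the control group. For the third flask array at 1 week the description mentions only 5 days, while its title and channel 2 source give 1 week; it was kept at 1 week.

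The values are log2 ratios that were lowess corrected by the authors, per the labels. The scanner, the background correction and the dyes are not given in the sources used here. The median of each array lay between −0.02 and 0.01, so the arrays were centred as deposited. The scale was stated as log2, but which channel is the numerator was not stated. The table held 3024 rows, with 52 of 96768 cells empty. No intensities were given, so signal over background is unknown and the number of arrays limits the precision. The lowest correlation between any pair of arrays over all rows was −0.179 and the highest was 0.781.

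Gene names came from the platform annotation. Of the rows, 1332 had 1 gene symbol, 4 had several and 1688 had none. Symbols were checked against the RefSeq gene table of GRCh38.p14, used for names alone. Rows of one symbol were averaged into 311 symbols, of which 308 are single human genes, and each row without a symbol stayed as a feature of its own, giving 1999 features. A feature needed a value on at least 22 arrays, which left out 0 features. Counts of changed genes below are counts of named genes, while the p-value adjustment runs over all features.

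A single linear model with 12 groups was fitted to all arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. It had 20 residual degrees of freedom, 6.48 prior degrees of freedom and a prior SD of 0.172. Each later time was set against the 5-day arrays of its format, which subtracts a probe's dye effect only as far as it was alike on both sets of arrays. An F test asked whether a gene changed at any time, and contrasts of contrasts compared the 3-week change between formats. Features with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The labels do not say whether replicates were separate cultures, so the p-values of this model measure the spread between these arrays, which may be technical.

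Before the data were examined, 27 gene lists, the groups, the tests, most alternatives and the rule for named genes were fixed. The lists with at least 5 measured members were tested at 3 weeks with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The rule names, at 3 weeks, the 12 largest changes in each direction among called genes whose every 3-week array lies on the same side of every 5-day array of that format. At 1 and 2 weeks it names the 4 largest by the same test, for each difference between formats the 5 largest called, for each list called by camera up to 4 members, and every measured member of the lists used for the direction of the ratio. Genes named to spell out a count of list members or shared genes (SCN10A at 3 weeks, TRPC4, GNAI3 in flasks and SLC23A1 in filters A among them), and the filters B values of the genes that flasks and filters A share, fall outside the rule and were chosen after their values were seen. Alternatives covered centring, scaling to a common spread, missing values, single rows, the arrays in the fit, a block for replicate number, tests against 0 without the 5-day arrays, array weights, a robust prior and leaving out each replicate number. Others were chosen after seeing the data: unnamed rows averaged in blocks of 4, named genes alone, 5-day arrays of all formats as control, removal of a flask 5-day pattern, and arrays in doubt left out. Rows lay in blocks of 4, with a mean SD within blocks of 0.199 against 0.217 to 0.230 for blocks shifted by 1 to 3 rows.

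The steps were tested on simulated data with the residual spread of the real features and 1999 features in the fit. For the 3-week comparison in flasks, 46 of 50 named genes changed by 0.5 and 50 of 50 changed by 1 were recovered, with 0 false calls among 211 unchanged named genes. For filters A at 3 weeks the numbers were 45 and 49, with 1 false call, and for filters B at 3 weeks 36 and 48, with 0. The simulated noise was normal, independent between features and alike in spread on every array. As many unnamed rows as named genes were shifted too, in all more features than were called at 3 weeks in any format. The p-value adjustment is easier to pass when more features change, and in filters B 0 features were called at 3 weeks. Estimated weights of the real arrays ran from 0.36 to 2.64. For both reasons recovery on the real arrays may be lower. Of the 19 simulated list tests in flasks, 1 was called, and it was the list that had been shifted.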

Results

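The arrays measured 311 named genes and 1688 unnamed rows in Caco-2 cells in 3 culture formats and at 4 times. The number of arrays, 2 or 3 per group, limits the precision. The median 95% confidence interval of a named gene's change extended 0.22 to either side in flasks and filters A and 0.27 in filters B, on the log2 scale.

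Because the numerator was not stated, the direction was taken from gene lists fixed beforehand: 11 genes described as rising as enterocytes differentiate and 8 described as falling as cells stop dividing. At 3 weeks the median change of the rising list lay above that of the falling list in every format, at 0.22 against −0.17 in flasks, 0.12 against −0.08 in filters A and 0.09 against 0.04 in filters B, where the mean of the falling list was of the other sign, at −0.04. The difference of the means was 0.64 in flasks (two-sided exact permutation p = 0.000542, adjusted p = 0.00163 over 3 formats), 0.50 in filters A (exact p = 0.0549, adjusted p = 0.0823) and 0.10 in filters B (exact p = 0.469). The permutation moved genes between the lists, so it takes genes as independent and does not measure the spread between arrays. Camera with an estimated correlation between genes gave adjusted p = 0.567 for each of the lists in flasks. By the rule fixed beforehand, a positive value is read as likely higher at the later time, and "rose" and "fell" are used in that sense throughout.

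The comparison of flasks at 3 weeks with 5 days asked which transporter and channel genes change as the culture ages. FXYD3, a regulator of the sodium pump, rose by 1.95 (SE 0.32, adjusted p = 0.000834), a 3.87-fold change. VTN, the adhesion protein vitronectin, rose by 1.44 (SE 0.25, adjusted p = 0.00112), and SLC11A2, which carries ferrous iron into cells, rose by 1.25 (SE 0.25, adjusted p = 0.00488). SLC7A5, a carrier of large neutral amino acids, fell by 1.51 (SE 0.26, adjusted p = 0.00112), and SLC38A1, a glutamine carrier, fell by 1.03 (SE 0.19, adjusted p = 0.00169). Each group had 3 arrays, and 25 named genes changed, 6 up and 19 down, with 39 unnamed rows.

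The other risen genes were SLCO2B1, an organic anion carrier (0.61), ABCA1, which exports cholesterol (0.59), and SLC23A1, a vitamin C carrier (0.57), with adjusted p from 0.00968 to 0.0202. Among the falling genes were TIMM23 (−0.90) and TIMM17A (−0.67), parts of the protein import machinery of the mitochondrial inner membrane, the glucose carrier SLC2A3 (−0.89), the glutamate carrier SLC1A3 (−0.83) and the peroxisomal ABCD3 (−0.74). YWHAZ, a 14-3-3 protein, changed by −0.78, KPNA2, an importin alpha, by −0.66 and GRK6, a receptor kinase, by −0.61. The cytoskeletal genes ACTB and TUBA1B stood at −0.73 and −0.61. The SEs of these genes ran from 0.12 to 0.17. The 2 sets of 4 spots for SLC7A5 gave −0.94 and −2.08. Scaling the arrays to a common spread left 6 of the 25 genes called, fitting the flask arrays alone left 16, and without replicate 3 there were 13 calls, 10 of them among the 25.

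By list, 3 of 17 amino acid and peptide carriers fell in flasks (SLC7A5, SLC38A1 and SLC1A3), and 2 of 10 mitochondrial carriers and import genes fell. In the list of 12 genes of P-type pumps and their subunits 1 rose, the pump regulator FXYD3, which is not itself a pump. Of 16 ATP-binding cassette genes 1 rose (ABCA1) and 1 fell (ABCD3), and 1 of 10 sugar carriers fell (SLC2A3). SLC11A2 was the 1 of 7 metal carriers that rose, SLCO2B1 the 1 of 12 organic ion carriers and SLC23A1 the 1 of 8 nucleoside and vitamin carriers. SCN10A, a sodium channel, was the 1 of 16 voltage-gated sodium and calcium channels that fell (−0.51). When the lists were fixed, these channels and the neurotransmitter carriers were described as markers of neural cells that an epithelial line should lack. What the probes of these 2 lists read in these cells was not tested. None of the 24 potassium channels, 22 electrolyte exchangers, 11 TRP channels, 7 connexins, 6 chloride channel genes or 8 genes of colonic surface cells passed the threshold. Adjusted over the list alone, the counts were 0 up and 3 down for amino acid carriers, 0 and 3 for mitochondrial genes, 2 and 2 for the ATP-binding cassette genes, 1 and 1 each for P-type pumps, organic ion carriers and sodium and calcium channels, 0 and 1 for sugar carriers, and 1 and 0 each for metal carriers and for nucleoside and vitamin carriers. The same count was 0 and 1 for chloride channel genes, and 0 and 0 for each of the potassium channels, electrolyte exchangers, TRP channels, connexins and genes of colonic surface cells.

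Among the 19 lists tested in flasks, camera called 1, the list of genes described as falling as cells stop dividing (adjusted p = 0.0341). The call was lost with an estimated correlation, where the list's adjusted p = 0.567, and this list also served to set the direction of the ratio. Of its 8 members 3 fell, SLC7A5, SLC38A1 and SLC2A3, and 3 also fell when adjusted over the list alone, while SLC25A5, a mitochondrial ADP/ATP carrier, stood at −0.17 (adjusted p = 0.550). SLC1A5, a glutamine carrier, stood at −0.16, KCNH2 at −0.16, SLC2A1 at 0.03 and SLC29A1 at 0.01, none past the threshold. Of the 11 genes described as rising, 0 passed the threshold in flasks: SLC26A3 stood at 0.37, SLC10A2 at 0.31, CDH17 at 0.28, SLC2A5 at 0.24, SLC40A1 at 0.23, SLC15A1 at 0.22, ABCG5 at 0.19, SLC5A1 at 0.16, SLC2A2 at −0.07, ATP2B1 at −0.10 and ABCG8 at −0.17. fry, which asks whether a list's genes move one way on balance, gave adjusted p = 0.0311 for this list, which also served to set the direction of the ratio and of which 0 members passed when adjusted over the list alone. It gave adjusted p = 0.00440 each for the falling list, the mitochondrial genes and the bile acid and lipid carriers, of which 1 of 7 rose (ABCA1; 1 up and 0 down adjusted over the list alone), and adjusted p = 0.0337 for the 10 neurotransmitter carriers, of which 0 passed, also when adjusted over the list alone.

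Earlier in flasks, SLC7A5 and SLC38A1 already differed from 5 days at 1 week, by −1.21 (SE 0.26, adjusted p = 0.0102) and −0.89 (SE 0.19, adjusted p = 0.00899). SCN10A, on the list of channels described as markers of neural cells, fell by 0.82 (SE 0.12, adjusted p = 0.000410) and ACTB by 0.75. SLC10A2, the ileal bile acid carrier, rose by 0.42 (SE 0.12, adjusted p = 0.0478). In all 10 named genes changed at 1 week, 1 up and 9 down, and 27 at 2 weeks, 8 up and 19 down. At 2 weeks FXYD3 rose by 1.90, VTN by 1.39, SLC11A2 by 0.99 and ATP1B1, a sodium pump subunit, by 0.80, while SLC7A5 fell by 1.69, ACTB by 1.21, TUBA1B by 1.17 and SLC2A3 by 0.99, with adjusted p of 0.0295 or less. Over all times 28 named genes changed by the F test, against 9 without replicate 3. The 1-week count was 1 without replicate 3 throughout, 5 without replicate 1, and 5 without the 1-week array whose description mentions 5 days; the 2-week count was 9 without replicate 3.

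**Figure D1:**
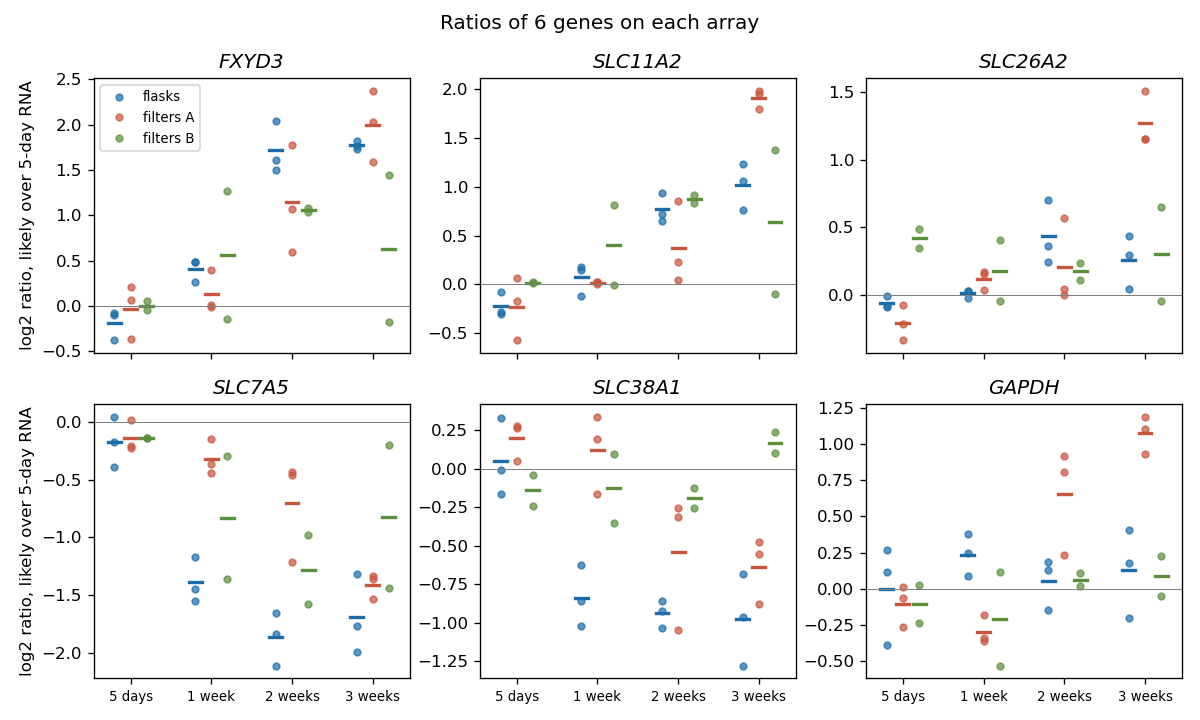
The log2 ratio of 6 genes on every array is plotted against time for flasks, filters A and filters B; points are arrays and short bars are group means. FXYD3 and SLC11A2 lie above their 5-day arrays at 3 weeks in flasks and filters A, SLC7A5 lies below them, and the filters B arrays at 1 and 3 weeks lie far apart for FXYD3 (SD 0.99 and 1.14, n = 2).

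In filters A at 3 weeks SLC11A2 rose by 2.14 (SE 0.25, adjusted p = 3.66e-06), a 4.42-fold change, and FXYD3 rose by 2.03 (SE 0.32, adjusted p = 0.000184). SLC26A2, a sulfate carrier, rose by 1.48 (SE 0.16, adjusted p = 3.08e-06), and the chloride and bicarbonate exchanger SLC26A3 rose by 0.96 (SE 0.15, adjusted p = 0.000139). SLC40A1, which exports iron, and SLC2A5, a fructose carrier, rose by 0.85 and 0.91. SLC7A5 fell by 1.27 (SE 0.26, adjusted p = 0.00371) and SLC38A1 by 0.83 (SE 0.19, adjusted p = 0.00733). In all 39 named genes changed, 19 up and 20 down, from 3 arrays per group, with 76 unnamed rows.

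VTN also rose in filters A, 2.82-fold, as did ATP1B1 (1.23), SLCO2B1 (1.11), the cell adhesion gene CDH17 (0.68) and GAPDH, a glycolytic enzyme (1.18, SE 0.19). SLC6A10P rose by 0.77, but it is a pseudogene nearly identical to the creatine carrier SLC6A8, so its probe's target is uncertain. The falling genes included KPNA2 (−0.83) and KPNA3 (−0.61), both importin alphas, SLC1A3 (−0.81), ABCE1, a ribosome recycling factor (−0.72), TIMM17A (−0.56), TIMM23 (−0.51), the G protein subunit GNAI3 (−0.52), the potassium channel KCNK9 (−0.52), the mitochondrial carrier SLC25A13 (−0.47) and the organic anion carrier SLC22A11 (−0.45). The adjusted p of these genes was 0.0404 or less. The count was 24 without 5-day replicate 2, 17 without replicate 3 at every time and 18 without replicate 2 at every time.

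Of the 11 genes described as rising with differentiation, 4 rose in filters A: SLC26A3, SLC2A5, SLC40A1 and CDH17. Adjusted over the list alone 5 rose and 1 fell, since SLC15A1, a peptide carrier, stood at 0.26 and SLC5A1, the sodium and glucose cotransporter, at −0.34. The others stood at 0.12 for ATP2B1, 0.00 for ABCG5, −0.15 for SLC10A2 and −0.18 for both SLC2A2 and ABCG8. Camera gave adjusted p = 0.364 for this list and fry adjusted p = 0.00154. This list and the falling list served to set the direction of the ratio, so their movement in the described directions is partly built in. Of the 8 genes described as falling 2 fell, SLC7A5 and SLC38A1, with adjusted p = 0.895 by camera; adjusted over the list alone 1 rose and 2 fell. SLC1A5 stood at 0.35, SLC2A1 at 0.23, SLC29A1 at 0.17, KCNH2 at −0.03, SLC25A5 at −0.12 and SLC2A3 at −0.35, none past the threshold over all features.

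By list in filters A, 2 of 7 metal carriers rose (SLC11A2 and SLC40A1), and 2 of 22 electrolyte exchangers rose (SLC26A2 and SLC26A3), which are also 2 of the 8 genes of colonic surface cells. In the list of 12 genes of P-type pumps and their subunits 2 rose, the regulator FXYD3 and the subunit ATP1B1. Of 17 amino acid and peptide carriers 1 rose and 3 fell, and 3 of 10 mitochondrial genes fell. Of 8 nucleoside and vitamin carriers 2 rose and 1 fell, of 16 ATP-binding cassette genes 2 fell, and of 24 potassium channels 2 fell. Of 12 organic ion carriers 1 rose and 1 fell, 1 of 10 sugar carriers rose, and 1 of 16 sodium and calcium channels and 1 of 6 chloride channel genes fell. None of the 7 bile acid and lipid carriers, 10 neurotransmitter carriers or 7 connexins passed. Adjusted over the list alone the counts were 2 up and 0 down for metal carriers, 2 and 0 for electrolyte exchangers, 2 and 0 for P-type pumps, 3 and 4 for amino acid carriers, 1 and 3 for mitochondrial genes, 2 and 1 each for genes of colonic surface cells and for nucleoside and vitamin carriers, and 0 and 2 each for ATP-binding cassette genes and potassium channels. They were 3 and 3 for organic ion carriers, 1 and 1 each for sugar carriers and chloride channel genes, 0 and 1 for sodium and calcium channels, 1 and 0 for neurotransmitter carriers, and 0 and 0 each for bile acid and lipid carriers and for connexins. Camera called 0 of the 19 lists in filters A, and fry called the TRP channels as well (adjusted p = 0.00392), of which 1 of 11 fell (TRPC4), also when adjusted over the list alone.

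Filters A at 1 week showed 8 changed named genes, 4 up and 4 down, and 111 unnamed rows. SLC16A7, a monocarboxylate carrier, rose by 0.70 (SE 0.16, adjusted p = 0.0149), RGS1, a regulator of G protein signalling, rose by 0.52 and SLC4A4, a sodium bicarbonate cotransporter, rose by 0.40. CLNS1A fell by 0.44, KCNK1, a potassium channel, by 0.38, the dopamine receptor DRD2 by 0.35 and RGS5 by 0.31, with adjusted p from 0.0238 to 0.0345. At 2 weeks 10 named genes changed, 3 up and 7 down. FXYD3 rose by 1.18, the mitochondrial BNIP3 by 0.77 and GAPDH by 0.76, and SLC38A1 fell by 0.74, ABCE1 by 0.69, the calcium channel CACNA1C by 0.55 and the arginine carrier SLC7A1 by 0.48, with adjusted p of 0.0432 or less. Replicate 3 stood apart at 2 weeks on the 12 genes called at 3 weeks in both flasks and filters A. Their mean ratio, each signed by its flask change, was 0.81 there against 0.24 and 0.30 on replicates 1 and 2. Over all times 49 named genes changed by the F test, against 13 without replicate 2 and 15 without replicate 3. The 1-week count was 0 without 5-day replicate 2, 0 without 5-day replicate 3, 0 after scaling and 22 without replicate 1 at every time; the 2-week count was 1 and 3 without those 5-day arrays, and at every time 17 without replicate 1 and 0 without replicate 2 or 3.

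In filters B, the one gene that changed was SCNN1B, a subunit of the epithelial sodium channel, which fell by 0.81 at 2 weeks (SE 0.16, adjusted p = 0.0194). With 2 arrays per group, limma called 0 named genes at 1 week, 1 at 2 weeks and 0 at 3 weeks, against 16, 25 and 16 at an unadjusted p under 0.05, and the F test called 0 against 19. Counts of 16 are close to the share of 0.05 of 311 genes that no change would give, and 19 is not far above it. Of the 12 genes called at 3 weeks in both flasks and filters A, the 5 that rose there stood above 0 in filters B, FXYD3 at 0.63, SLC11A2 at 0.62, VTN at 0.53, SLCO2B1 at 0.30 and SLC23A1 at 0.17. Of the 7 that fell there, SLC7A5 stood at −0.68 (SE 0.32), KPNA2 at −0.54 and SLC1A3 at −0.07, but SLC38A1 at 0.31, TIMM17A at 0.14, GNAI3 at 0.13 and TIMM23 at 0.07. Of the other members of the falling list SLC2A3 stood at 0.39, SLC2A1 at −0.32, SLC1A5 at −0.20, KCNH2 and SLC25A5 at 0.12, and SLC29A1 at −0.05. Of the rising list, SLC26A3 stood at 0.39, CDH17 at 0.31, SLC2A5 at 0.22, SLC10A2 at 0.14, SLC15A1 at 0.11, ATP2B1 at 0.09, SLC40A1 at −0.02, SLC5A1 at −0.08, both SLC2A2 and ABCG8 at −0.14, and ABCG5 at −0.23, none past the threshold. Camera called 0 of the 19 lists. Replicate 1 at 1 and at 3 weeks stood apart from replicate 2, and without those 2 arrays the 3-week count was 8 and the F test count 7, with lone arrays assumed to vary like the other groups; SCNN1B was not called when replicate 1 or replicate 2 was left out at every time.

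In the fit over all features, SLC26A2 was the one named gene whose 3-week change passed the threshold between formats. Its change in filters A exceeded that in flasks by 1.17 (SE 0.23, adjusted p = 0.0105), and its change in filters B was below that in filters A, at −1.60 (SE 0.26, adjusted p = 0.00319). Both differences use the same filters A arrays. The number called depended on the features and arrays tested. Filters A minus flasks gave 1 named gene, against 60 at an unadjusted p under 0.05, 18 with named genes alone, and 18 with unnamed rows in blocks of 4. With only the compared arrays it gave 3, with array weights 2, and without replicate 1, 2 and 3 it gave 2, 0 and 0. Filters B minus filters A gave 1, against 45 unadjusted, 14 with named genes alone and 8 with blocks of 4. After scaling it gave 2, and without replicate 1, 2 and 3 it gave 0, 6 and 1. Between filters B and flasks limma called 0 named genes, against 43 unadjusted. It called 6 with named genes alone, 5 with blocks of 4, 5 with array weights and 4 without filters B replicate 1 at 1 and 3 weeks. SLC26A2 stood at 1.27 ± 0.21 (SD, n = 3) in filters A at 3 weeks, 0.26 ± 0.20 (n = 3) in flasks and 0.30 ± 0.49 (n = 2) in filters B, and at −0.21 ± 0.13 (n = 3), −0.06 ± 0.05 (n = 3) and 0.42 ± 0.10 (n = 2) on the 5-day arrays of filters A, flasks and filters B. The difference from flasks was not called without replicate 2 (adjusted p = 0.235) or replicate 3 (adjusted p = 0.139), nor that from filters B without replicate 1 (adjusted p = 0.123).

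Flasks and filters A shared 12 genes called at 3 weeks: FXYD3, VTN, SLC11A2, SLCO2B1 and SLC23A1 rose in both, and SLC7A5, SLC38A1, SLC1A3, TIMM23, TIMM17A, GNAI3 and KPNA2 fell in both. None was called in opposite directions. Independent lists of these sizes would share 0.367 rising and 1.22 falling genes. Fisher's exact test of the overlap of called genes, which ignored direction, gave p = 4.67e-06, with genes taken as independent. Both sets of calls used the same estimate of each gene's spread, which that test does not allow for. Across the 311 genes, which are not independent replicates, the 3-week changes correlated with Pearson's r = 0.64 and Spearman's rho = 0.41 between flasks and filters A, 0.43 and 0.20 between filters A and filters B, and 0.25 and 0.01 between flasks and filters B. Over all rows, the ratios of the filters B 3-week arrays correlated with the 3 filters A 3-week arrays at −0.04, 0.02 and −0.02 for replicate 1 and 0.44, 0.46 and 0.41 for replicate 2. With the flask 3-week arrays they correlated at 0.08, −0.05 and 0.05 and at 0.37, 0.16 and 0.33. These formats have their own 5-day arrays, so no control arrays are shared in these pairs.

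**Figure D2:**
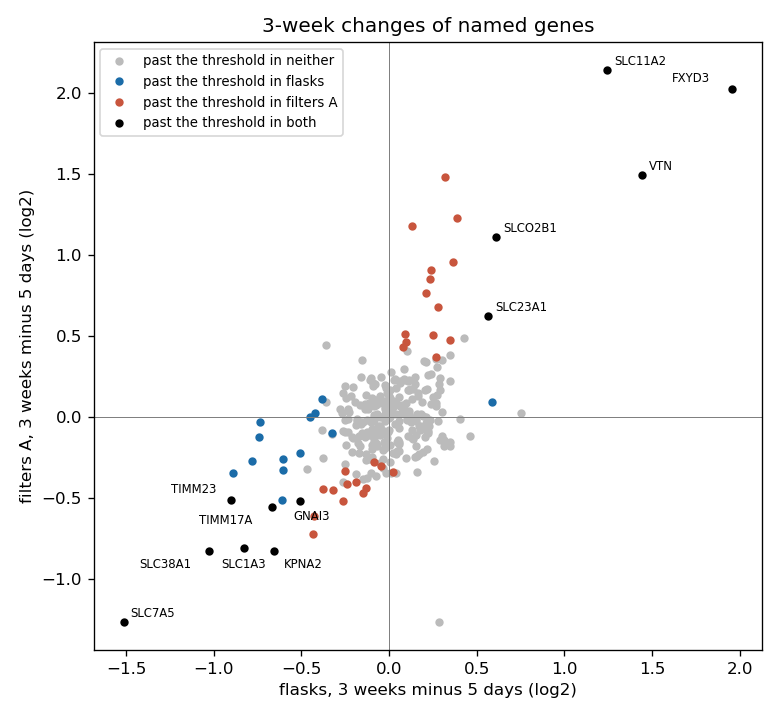
The 3-week change of each of 311 named genes in filters A (vertical, log2) is plotted against that in flasks (horizontal, log2), coloured by where it passed the threshold. The 12 genes called in both lie at the upper right and lower left, from SLC7A5 at −1.51 and −1.27 to FXYD3 at 1.95 and 2.03.

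**Figure D3:**
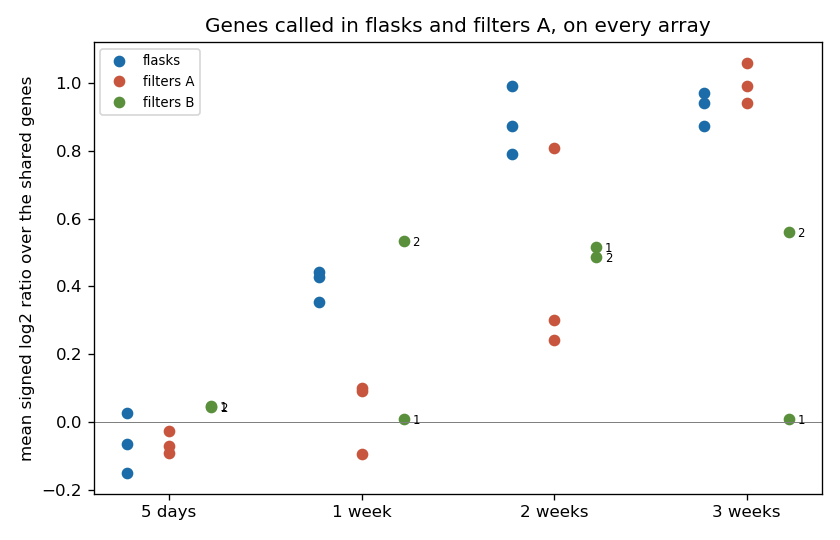
The mean log2 ratio over the 12 genes called in both flasks and filters A, each signed by its flask change, is plotted for every array by time and format; numbers beside filters B points are replicates. The 5-day arrays lie between −0.15 and 0.05, as do the replicate 1 arrays of filters B at 1 and 3 weeks and that of filters A at 1 week, while the other later filters B arrays lie between 0.49 and 0.56.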

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

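The splits of the samples were planned before their outcome was known. SLC26A2 stood out because its 3-week change differed between culture formats in a test of the difference itself, by 1.17 between filters A and flasks and by −1.60 between filters B and filters A. Part of both values comes from the 5-day arrays, where 5-day RNA compared with itself gave −0.21 in filters A, −0.06 in flasks and 0.42 in filters B for this gene. Of 100 splits of the flask and filters A arrays at 5 days and 3 weeks between the formats, 12 gave at least the 1 gene found, and the highest gave 10, so chance is not excluded for the number of differing genes. The other splits were not scored for SLC26A2 itself.

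Rows without a gene symbol lie outside the named comparisons, and 39 of them at 3 weeks in flasks and 76 in filters A differed from the 5-day control arrays. Averaged in blocks of 4 neighbouring rows, 34 and 61 of 422 blocks passed the threshold. They carry no name here, so no gene is given.

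For changes over time, 28 named genes in flasks were more than any of the other splits drawn gave, the highest being 16, and 1 of 100 splits, the real one, gave as many. In filters A 49 genes compared with a highest other value of 19, again 1 of 100. Chance assignment of arrays to times is excluded at that level for both, with each array taken as independent. The labels do not say whether replicates were separate cultures, so a difference shared by the arrays of one time for another reason is not excluded. For each single time, 6 arrays make 10 splits, too few for a share under 0.05. The real values and the highest of the other splits were 10 and 0 at 1 week in flasks, 27 and 0 at 2 weeks, 25 and 1 at 3 weeks, and in filters A 8 and 1, 10 and 0, and 39 and 0.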

How the results depend on the processing

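Centring, either filter on missing values and the robust prior left every count within 1.5 times of its reported value. Of 1003 values of named genes under alternatives, 841 stayed on the same side of the threshold, 148 fell short of it and 14 newly passed it. Among values past the threshold in either fit, 0 turned direction. Values past it in neither fit were counted among the 841 whatever their direction. Of those that fell short, 120 did so when a replicate number or arrays in doubt were left out. Counts of named genes are given below in the order 1, 2 and 3 weeks, and the cause was not tested unless the alternative itself changes the number of features or arrays. Scaling to a common spread gave 6 in flasks at 3 weeks, 0 in filters A at 1 week, 1 in filters B at 1 week, 6 at 2 weeks (1 up and 5 down, against 0 and 1), 2 over time and 2 for filters B minus filters A. Single rows, counted as rows, gave 48, 110 and 87 in flasks, 73, 57 and 142 in filters A, 1 in filters B at 3 weeks, 127, 214 and 3 over time in flasks, filters A and filters B, and 14, 12 and 6 for the differences filters A minus flasks, filters B minus flasks and filters B minus filters A. With the arrays of the compared formats alone, which leaves fewer degrees of freedom, the counts were 6 at 1 week and 16 at 3 weeks in flasks, 0 and 5 in filters A at 1 and 2 weeks, 0 in filters B at 2 weeks, 17 and 30 over time in flasks and filters A, and 3 for filters A minus flasks. Tested against 0 without the 5-day arrays, they were 33, 53 and 77 in flasks, 17, 20 and 61 in filters A, 15, 14 and 8 in filters B, 98, 87 and 41 over time, and 11, 18 and 15 for the differences. The list difference behind the direction became 0.54 in filters A, where its exact permutation p fell under 0.05 without adjustment over the 3 formats. In filters B that difference became 0.23 from 0.10, and its exact p did not fall under 0.05. The correlations became 0.76, 0.43 and 0.55 for flasks with filters A, flasks with filters B and filters A with filters B. Array weights gave 2 and 6 in filters A at 1 and 2 weeks, 11 in filters B at 2 weeks, 1 over time in filters B, and 2 and 5 for filters A and filters B minus flasks. The following were chosen after seeing the data. Blocks of 4 unnamed rows, which leave fewer features, gave 45 and 51 in flasks at 2 and 3 weeks, 22, 30 and 65 in filters A, 49, 92 and 1 over time, and 18, 5 and 8 for the differences. Named genes alone gave 52 and 57 in flasks at 2 and 3 weeks, 35 and 69 in filters A, 2 in filters B at 2 weeks, 54, 91 and 1 over time, and 18, 6 and 14 for the differences; all genes reported at 3 weeks in flasks (25) and filters A (39) were among them. With 5-day arrays of all formats as control there were 41 in flasks at 3 weeks, 1 in filters A at 1 week, 1, 7 and 1 in filters B and 2 over time. Without filters B replicate 1 at 1 and 3 weeks there were 2 at 2 weeks, 8 at 3 weeks, 7 over time and 4 for filters B minus flasks. Without filters A 5-day replicate 2 there were 0, 1 and 24, without 5-day replicate 3 there were 0 and 3 at 1 and 2 weeks, and without flasks 1-week replicate 3 there were 5 at 1 week and 27 over time. Leaving out each replicate number gave 1 to 8, 9 to 26 and 13 to 25 in flasks, 0 to 22, 0 to 17 and 17 to 33 in filters A, 0 to 2, 0 to 1 and 0 to 2 in filters B, 9 to 24, 13 to 47 and 2 to 4 over time, and 0 to 2, 0 to 1 and 0 to 6 for the differences, where a lone filters B array is assumed to vary like the other groups. Lists called at 3 weeks in flasks numbered 0 with an estimated correlation, after scaling or against 0, and 0 to 1 without a replicate number; in filters B 0 to 3 were called. Replicate numbers were not taken to pair the arrays: correlations of same-numbered deviations ran from −0.16 to 0.24 in flasks, −0.11 to 0.15 in filters A and −0.01 to 0.21 in filters B, and 6 of 12 arrays in flasks and 6 of 12 in filters A correlated best with their own number. With 2 arrays per group, as in filters B, deviations mirror each other and the best match says nothing more. The replicate block gave 4 for filters B minus flasks and 2 called lists in flasks, and it moved no other count by over 1.5 times. Intensities were not given, so what signal over background limits is unknown.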

Other observations

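The genes of this paragraph were chosen after their values were seen. The importin alpha genes, whose products carry proteins into the nucleus, lay below 0 at 3 weeks in flasks, at −0.61 for KPNA1, −0.66 for KPNA2, −0.43 for KPNA3, −0.45 for KPNA4 and −0.26 for KPNA6, and 3 of the 5 passed the threshold there (KPNA1, KPNA2 and KPNA4), while after scaling to a common spread all 5 stayed below 0 and 0 passed. In filters A KPNA2 and KPNA3 passed it, with and without scaling, and KPNA1 stood at −0.33, KPNA4 at 0.00 (below 0 after centring or scaling) and KPNA6 at −0.09. In filters B none passed, with KPNA2 at −0.54 and KPNA3 at −0.14, and with KPNA1 at 0.19, KPNA4 at 0.18 and KPNA6 at 0.04 (below 0 after scaling).

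All tests on the 2 patterns that follow were chosen after the result was seen. On the filters B arrays, the mean ratio over the 12 genes called in both flasks and filters A, each signed by its flask change, was near 0.01 for replicate 1 at 1 week and at 3 weeks, against 0.49 to 0.56 for the other later filters B arrays. The tables argue against labels swapped with a 5-day array, since the highest of the 8 5-day arrays stood at 0.046 and none was out of place. A candidate explanation that stays open is 5-day RNA in channel 2 of these arrays: the higher of the pair, 0.0093, lay within the 5-day range of −0.15 to 0.05. The genes were chosen for their difference from the flask and filters A 5-day arrays, which can lower the scores of those arrays. The filters B 5-day arrays stood at 0.043 and 0.046, above the pair. The SD over rows was 0.363 at 1 week and 0.237 at 3 weeks for the pair. It was 0.163 and 0.195 on the filters B 5-day arrays and 0.226 to 0.353 on the other 5-day arrays. Within blocks of 4 rows the SD was 0.338 and 0.198 for the pair, so much of their spread lay between neighbouring rows. It was 0.144 and 0.168 on the filters B 5-day arrays. Over all rows the pair correlated with each other at 0.41. They correlated at 0.27 to 0.37 with the filters B 5-day arrays and at 0.19 to 0.26 with the other later filters B arrays. Lying in the 5-day range is not particular to the pair, since filters A replicate 1 at 1 week lay in it at −0.09 and the other filters A arrays at 1 week stood at 0.09 and 0.10. A culture that had not changed by then would give the same values, no biological explanation was tested, and the arrays were kept in their groups.

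The filters A calls at 1 week, 8 named genes and 111 unnamed rows, disappear for named genes without 5-day replicate 2 or 3 (0 each). A dye pattern of the flask 5-day arrays left in the values was tested by removing each array's slope on it. For named genes 9 were then called, among them all 8, and for unnamed rows 96, of which 84 were among the 111. The pattern was the mean of 3 arrays that correlated with each other at 0.31 to 0.49. Its removal may therefore be incomplete, and these counts cannot decide whether it caused the calls. Of the 8 named calls, 5 had the sign of the pattern. The 1-week change correlated with it at −0.11 over named genes and 0.25 over unnamed rows. Of the unnamed calls, 79 had the sign of the pattern, so a part may come from it. Separate processing of these arrays cannot be told apart from the time point: the 3 arrays of this group were the ones given with more than 2 decimals, and 0 arrays of other groups were.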
